A study of Mus musculus with 96 samples.

How the data were processed

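Neural tubes of wild-type (C3HeB) and heterozygous Eif3c Xs-J mouse embryos at stage E11.5 were measured by ribosome profiling and by RNA-seq, with 3 pools per genotype in each assay. Per the labels' protocols, the RNA libraries were made from fragmented poly(A) RNA, and the footprint lysates, made in cycloheximide, were spun to remove nuclei and mitochondria before RNase I digestion. Per the submitters' processing notes, adapters were removed with cutadapt, reads were aligned with STAR to mm10, and bedtools was used; no versions are given in the sources used here. The deposited values are counts of reads per transcript and per part of the transcript (5' untranslated region, coding sequence, 3' untranslated region), made by the authors for each lane; strand, the position of a footprint used for counting and the treatment of reads that fit several genes are not given in the sources used here. The coding counts leave out the first 15 and the last 5 codons. The parts summed to 105% of the counts of whole transcripts, and 0.328% of counts belonged to no gene. Of 122941 transcript identifiers, 121271 matched GENCODE vM21 with their version and 1522 without it, and 148 had no gene; 22422 genes were held.

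Lanes and runs of a library were summed, as technical repeats. In 4 lane files of mutant footprint pool 1, from the first run, counts were present on 3 chromosomes at most, while none of the other 92 lane samples had an empty chromosome. These 4 were left out after the data were examined, although the design fixed before had all lanes summed, so that this library is the sum of 4 complete lanes (11.3M counts); with all lanes summed the footprint count was 9 genes (7 higher, 2 lower) in place of 34, and translational efficiency gave 0 genes with or without the pool as a block. For each gene, 1 transcript was used, that with the highest total count, as 65.7% of genes had several coding transcripts. Reads shared by near-identical genes, such as histones and globins, or by overlapping genes cannot be assigned to 1 of them here. Footprint depth was 11.3 to 59.2M coding counts and RNA depth 7.20 to 13.1M, and the biological coefficient of variation was 8.16% in RNA, 9.97% in footprints and 9.19% in the joint fit. Coding sequences made up 59.3% and 59.0% of RNA counts and 85.7% and 83.8% of footprint counts in wild type and mutant.

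Tests used R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and DESeq2 1.42.0 as an alternative; tables and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. RNA and footprints were each tested with edgeR's quasi-likelihood test over 6 libraries, and translational efficiency as the interaction of genotype and assay over 12, with TMM normalization (factors 0.951 to 1.07), filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. CPM are TMM-scaled, SD are between the 3 pools, and efficiency values per pool used a prior of 0.5 CPM. Log2 fold changes come from edgeR's fit. Their SE was calculated back from the test, as the absolute log2 change over the square root of the F statistic. The footprint to RNA ratio of wild type was tested in the same fit. Gene lists, 32 of them, were fixed before the data were examined; 31 could be tested with camera (preset correlation 0.01, at least 5 members), with the estimated correlation, fry and ranks as alternatives, and surface epithelium markers had too few members in RNA. Sex-linked genes were kept as a check and not tested. The tests, the lists, the genes named in each comparison and most alternatives were chosen before the data were examined.

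Named in each comparison were Eif3c, Ptch1, Gli1, Gli2, Gli3, Smo, Shh, Atf4 and Cdkn1a, and, of the genes with adjusted p under 0.05, non-overlapping groups and a mean of at least 5 CPM, the 10 largest rises and the 10 largest falls, leaving out predicted genes named by a number. Where fewer than 5 passed in a direction, the 5 of smallest p are given as values. Up to 4 members of smallest p are given per list. Replicate numbers were shared by RNA and footprint libraries of a pool, which per the labels' protocols came from the same cells. Deviations of pools from their group mean correlated between RNA and footprints at 0.242, 0.231 and 0.349 in wild type for pools 1, 2 and 3. In the mutant these values were 0.599, 0.523 and 0.308. Every pairing of different numbers was below 0, which decides little, since deviations from a mean of 3 pools sum to 0 for each gene. Because the libraries of a pool came from the same cells, the pool was also fitted as a block in translational efficiency.

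The tests were tried on simulated data with 200 changed genes at the depth and average spread of these libraries. Each library was drawn independently, with no effect shared by the libraries of a pool, no GC trend and no pool set apart. Recovery in efficiency was the same with and without the pool as a block, so these shares do not cover the pool effects of the real data. At a fold of 1.5, 2, 3 and 4 the share of changed genes recovered was 68%, 96%, 96% and 98% in RNA, 68%, 92%, 98% and 100% in footprints and 44%, 74%, 92% and 98% in translational efficiency, with 9, 9 and 7 unchanged genes called. GC offsets took a simulated trend of rho 0.336 to -0.00177 and recovered 93.6% of changes of fold 4. GC content was that of the coding sequence of 21503 genes, 97.5% of which started with ATG. Alternatives were other scalings, filters and tools, blocks, leaving out each pool, each run alone, other ways to count a gene, and, chosen after seeing the data, the truncated lanes included, whole coding sequences and offsets for GC content or coding length.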

Results

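Ribosome profiling, which sequences the mRNA fragments that ribosomes protect from nuclease, and RNA-seq of poly(A) mRNA were carried out on neural tubes of mouse embryos at stage E11.5. Wild-type embryos (C3HeB) were compared with embryos heterozygous for the Eif3c Xs-J allele. Eif3c encodes a subunit of eIF3, the initiation factor complex that binds the small ribosomal subunit. Per the labels' protocols, dissociated cells of neural tubes from 1 litter were divided between a tube for RNA and a tube for footprints. Each RNA library therefore has a footprint library of the same cell pool. There were 3 pools per genotype and 12 libraries, each sequenced in 2 runs of 4 lanes, which gave 96 samples. Pools 1, 2 and 3 are those that the labels number TC1, TC5 and TC6, numbers that wild-type and mutant libraries share. The labels do not say what a shared number means, nor that the pools of a genotype came from separate litters, so the p-values measure the spread between these pools. Counts in trimmed coding sequences came to 8.60, 13.1 and 7.20M for wild-type RNA and to 13.1, 9.57 and 10.2M for mutant RNA (pools 1, 2 and 3). They came to 59.2, 17.3 and 32.8M for wild-type footprints, and 11.3, 12.1 and 14.8M for mutant footprints. Mutant footprint pool 1 rests on 4 complete lanes. Lanes and runs of 1 library differed by little more than sampling noise. The median chi-square per degree of freedom was 1.01 to 1.03 between lane samples, and the values between summed runs were 1.01 to 1.06. Libraries of 1 group differed by more (at least 2.26 in wild-type RNA, 5.51 in mutant RNA, 5.85 in wild-type footprints and 14.2 in mutant footprints). Mutant pool 1 stood apart from the other pools on the first principal component in RNA (27.6, against -3.79 and 12.5 for the other mutant pools and -14.3 to -10.9 for wild type). It also did so in footprints (35.9, against -5.21 and 12.8, and -15.7 to -12.7).

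The series' title names translational control of signalling transcripts through eIF3c in tissue patterning, and the first comparison asked which mRNAs differed in level between the genotypes. Eif3c mRNA (ENSMUSG00000030738.11, mm10 chromosome 7, 126546455 to 126566411, counted over its coding exons) was lower in every mutant library, at 295 ± 5.85 CPM against 496 ± 21.3 CPM in wild type (SD, n = 3 per genotype). The log2 change was -0.75 ± 0.06 (SE, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 6.15e-04). Ccnd2 (chromosome 6, 127125162 to 127152193), the D-type cyclin of cycling progenitors, rose from 100 ± 5.91 to 190 ± 39.3 CPM (log2 change 0.93 ± 0.13, edgeR adjusted p = 0.0365). The mitotic kinase Aurka rose from 57.3 ± 2.80 to 79.8 ± 4.46 CPM (0.48 ± 0.07, edgeR adjusted p = 0.0365). The p53-induced cyclin Ccng1 rose from 26.8 ± 1.49 to 39.9 ± 3.92 CPM (0.57 ± 0.10, edgeR adjusted p = 0.0391). Reln, a secreted protein that guides migrating neurons, fell from 235 ± 11.6 to 123 ± 41.7 CPM (-0.93 ± 0.17, edgeR adjusted p = 0.0394). The corepressor Skor1 fell from 88.2 ± 16.9 to 45 ± 11.7 CPM (-0.97 ± 0.16, edgeR adjusted p = 0.0377), and the homeobox factor Otp fell from 78.2 ± 5.47 to 49.2 ± 8.15 CPM (-0.68 ± 0.11, edgeR adjusted p = 0.0365).

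In all, 52 of 13406 genes differed in RNA, 30 higher and 22 lower, and 2351 had an unadjusted p under 0.05. The balance of directions turned under other fits, with 130 higher and 265 lower with DESeq2, 41 and 46 with limma-voom, 170 and 292 with no filter, 61 and 135 with a replicate block, and 564 and 964 without mutant pool 2. The other named rises were Hbb-bt (1.23), an adult beta-globin gene whose reads can be shared with its near-identical neighbour Hbb-bs, Fndc3c1 (0.70) and Ppat (0.51), which catalyses the first step of purine synthesis. They also included the ribosomal protein gene Rps20 (0.51), the mitotic regulator Fbxo5 (0.48), Ifrd1 (0.48) and the kinetochore gene Zwilch (0.46). Their standard errors ran from 0.06 to 0.20 and their edgeR adjusted p from 0.0365 to 0.0448. The other named falls were the corepressor Skor2 (-0.93), Tma7 (-0.85), the proteoglycan Spock1 (-0.77), Lxn (-0.76), an inhibitor of carboxypeptidases, Kif26b (-0.67) and Dner (-0.67), a transmembrane protein with Notch-ligand-like repeats. Their standard errors ran from 0.11 to 0.16 and their edgeR adjusted p from 0.0365 to 0.0391. Among the genes fixed in advance, none but Eif3c passed in RNA. The Hedgehog receptor Ptch1 had a log2 difference of -0.12 ± 0.08, its targets and effectors Gli1 of 0.24 ± 0.13, Gli2 of 0.08 ± 0.08 and Gli3 of 0.10 ± 0.06. The signal transducer Smo had a difference of 0.09 ± 0.07, the ligand Shh of 0.32 ± 0.17, the stress factor Atf4 of 0.11 ± 0.08 and the p53 target Cdkn1a of 0.57 ± 0.18 (edgeR adjusted p from 0.139 for Cdkn1a to 0.637 for Gli2). Gli2 turned to -0.0032 without mutant pool 3, and Cdkn1a passed in 1 of 18 alternatives. Leaving out 1 pool leaves 2 in its group, and the cause of the shifts in count that followed was not tested. The count of 52 moved widely in those fits. It was 2 without wild-type pool 1 and 1 without wild-type pool 2, wild-type pool 3 or mutant pool 3, with Eif3c among those left each time. It was 75 without mutant pool 1 and 1528 without mutant pool 2. With offsets for coding GC content, chosen after seeing the data, 2 genes passed, Ccnd2 and Eif3c. The other 18 genes named as changed lost the call (edgeR adjusted p from 0.0698 to 0.131) with a median absolute log2 change of 0.64 (median SE 0.12) against 0.68 (0.11) before, 14 of the 18 folds being smaller.

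**Figure D1:**
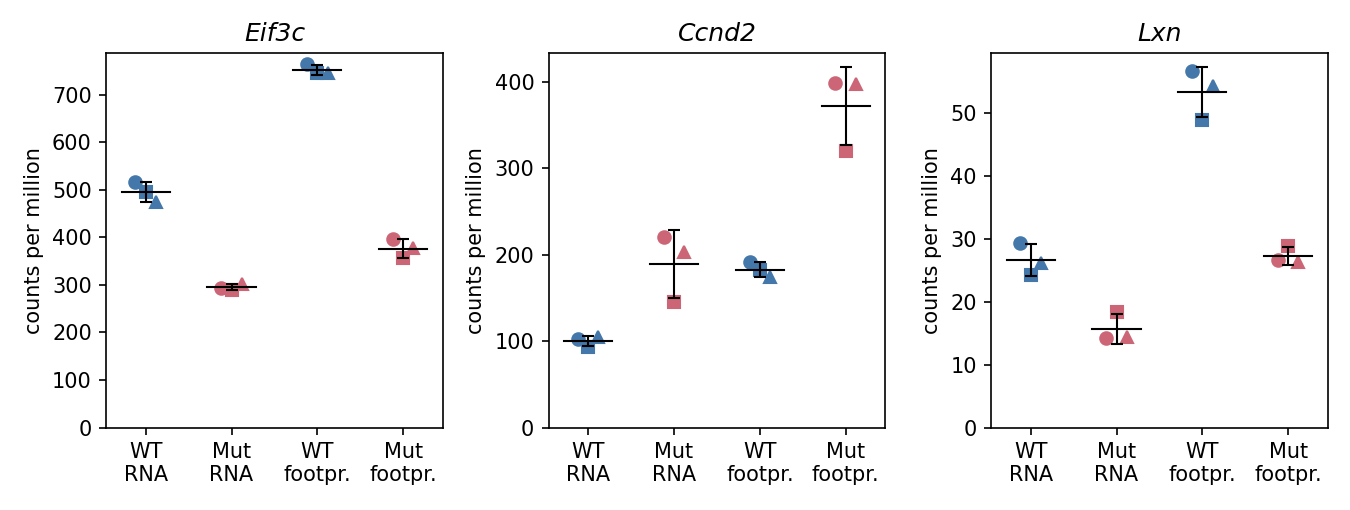
CPM (TMM scaled counts) of Eif3c, Ccnd2 and Lxn in RNA and footprint libraries of wild type (blue) and mutant (red), 1 marker per pool (circle 1, square 2, triangle 3), with the mean (line) and SD (bars) of 3 pools. Eif3c RNA lay at 295 CPM in the mutant against 496 CPM in wild type, and its footprints at 376 against 751 CPM.

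As lists, cell cycle genes were higher and pan-neuronal genes lower in mutant RNA with camera's preset correlation, and not with an estimated one. Of 45 cell cycle genes measured, 4 rose (Aurka, Ttk 0.41 ± 0.07, Hells 0.42 ± 0.07 and Kif11 0.36 ± 0.06) and 41 did not pass, while 37 rose adjusted over the list alone. All 45 log2 changes were positive, with a median of 0.26 (camera adjusted p = 1.81e-28, adjusted p = 0.558 with an estimated correlation). Of 40 pan-neuronal genes, which shape axons and synapses, none passed over all genes and 24 fell and 1 rose adjusted over the list alone. Their median was -0.23 (camera adjusted p = 4.07e-14, adjusted p = 0.558 with an estimated correlation). The microtubule protein gene Mapt had a log2 difference of -0.59 ± 0.12, the axon guidance receptor Robo2 of -0.69 ± 0.14, Gap43 of -0.27 ± 0.06 and Ina of -0.38 ± 0.09 (edgeR adjusted p from 0.0580 to 0.0669). Hox genes, which set position along the body axis, had a median of -0.23 over 34 genes, with 13 lower adjusted over the list alone and none over all genes (camera adjusted p = 5.85e-08, adjusted p = 0.558 with an estimated correlation). The smallest p were those of Hoxb8 (-0.43 ± 0.09) and Hoxc8 (-0.41 ± 0.09). The 40 postmitotic spinal neuron subtype factors had a median of -0.10 with 4 lower adjusted over the list alone (Pax2 -0.58, Pax8 -0.67, Lbx1 -0.47 and Pou3f1 -0.37, camera adjusted p = 0.00656, adjusted p = 0.742 with an estimated correlation). Their camera adjusted p was 0.0782 without wild-type pool 2 and 0.0922 without mutant pool 3. The 26 neural progenitor genes had a median of 0.01 with 1 riser, Ccnd2 (camera adjusted p = 0.421).

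The 21 erythroid markers had a median of 0.48, with Hbb-bt passing and 7 higher adjusted over the list alone (camera adjusted p = 1.18e-07, adjusted p = 0.725 with an estimated correlation). Their summed RNA was 6878 CPM in mutant pool 1 against 3841 and 3177 CPM in the other mutant pools and 3049 to 3732 CPM in wild type. Endothelial markers also stood highest in mutant pool 1 (948 CPM against 574 to 686 CPM in the other 5 libraries, list median 0.15, camera adjusted p = 0.215). Among 35 p53 targets, Eda2r (3.04 ± 0.50) and Ccng1 rose, and 4 rose adjusted over the list alone (median 0.11, camera adjusted p = 8.40e-05, adjusted p = 0.228 with an estimated correlation). Eda2r had a mean under 5 CPM and was therefore not among the largest rises named above. Initiation and elongation factors other than eIF3 had a median of 0.13 over 43 genes, with 6 higher adjusted over the list alone and none over all genes (camera adjusted p = 1.05e-05, adjusted p = 0.725 with an estimated correlation). The 12 eIF3 subunits had a median of 0.12 with Eif3c the only one past the threshold over all genes (camera adjusted p = 0.408). Adjusted over the list alone Eif3e was higher (0.27 ± 0.07).

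In 5 further lists the camera adjusted p in RNA was under the threshold and was lost when single pools were left out. Dorsal progenitor domain factors (24, median 0.20, adjusted p = 0.0221) had 5 higher and 1 lower adjusted over the list alone, led by the roof plate genes Wnt1 (0.73), Msx1 (0.74) and Gdf7 (1.47) and by Atoh1 (0.71). Their adjusted p was 0.0772 and 0.202 without wild-type pools 1 and 2 and 0.0729 and 0.104 without mutant pools 1 and 2. Ventral progenitor domain factors (16, median 0.19, adjusted p = 0.0230) had none passing. Their adjusted p was 0.122 and 0.165 without wild-type pools 1 and 3 and 0.163 and 0.0976 without mutant pools 1 and 3. Immediate early genes (22, median 0.30, adjusted p = 0.0149) had none passing. Their adjusted p was 0.270 and 0.0940 without wild-type pools 1 and 2 and 0.631 without mutant pool 1. Cytosolic ribosomal proteins (80, median 0.14, mean 0.01, adjusted p = 0.0167) had 1 riser, Rps20. Their adjusted p was 0.249 and 0.266 without wild-type pools 2 and 3 and 0.132, with the direction turned, without mutant pool 1. Heat shock and unfolded protein response genes (29, median 0.12, adjusted p = 0.00285) had none passing, and adjusted p was 0.111 without mutant pool 3. With an estimated correlation these 5 lists had adjusted p of 0.725 for heat shock and 0.861 for the others. The remaining lists did not pass in RNA, with camera adjusted p from 0.0635 to 0.847. They were replication-dependent histones (median 0.23), the Notch pathway (-0.02, with Dner lower), mitochondrially encoded genes (0.09), notochord markers (0.34), the BMP and TGF-beta pathway (-0.02) and macrophage and microglia markers (-0.16). Others were nuclear-encoded oxidative phosphorylation (0.03), integrated stress response targets (0.06), the FGF pathway (-0.02), mesenchyme and somite markers (0.04) and the retinoic acid pathway (-0.00). The last were cholesterol synthesis (median -0.02, mean 0.02), the Wnt pathway (median -0.01, mean 0.05), neural crest, sensory ganglion and Schwann cell markers (0.03), and the Hedgehog pathway. The Hedgehog median of 0.00 over 39 genes took either sign depending on the scaling, and its mean was -0.00 (camera adjusted p = 0.761).

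The second comparison asked which genes differed in ribosome footprints. Eif3c footprints were 376 ± 20.3 CPM in the mutant against 751 ± 10.9 CPM in wild type (log2 change -0.98 ± 0.07, edgeR adjusted p = 0.00131). Ccnd2 footprints rose from 183 ± 8.75 to 373 ± 44.9 CPM (1.04 ± 0.10, edgeR adjusted p = 0.00268). Those of Trim71 (chromosome 9, 114507133 to 114564369), an RNA-binding ubiquitin ligase of early embryonic cells, rose from 5.07 ± 1.18 to 15.2 ± 3.32 CPM (1.64 ± 0.21, edgeR adjusted p = 0.0161). Several replication-dependent histone genes, whose proteins package newly made DNA, rose. Hist1h4k rose by 1.46 ± 0.11, Hist2h3b by 1.31 ± 0.12, Hist1h4j by 1.16 ± 0.10, Hist1h2aa by 1.16 ± 0.17, Hist1h4b by 1.08 ± 0.10, Hist1h2ai by 1.06 ± 0.11 and Hist1h2bp by 0.96 ± 0.11 (edgeR adjusted p from 0.00131 to 0.0259). Histone genes share near-identical sequence and the counts of a single copy are uncertain. With whole coding sequences Hist2h3b stood at 0.26 ± 0.17 (edgeR adjusted p = 0.358) and Hist1h2bp at 0.52 ± 0.15 (0.101), and neither passed. Fignl2, a relative of microtubule-severing enzymes, rose by 1.37 ± 0.18 (edgeR adjusted p = 0.0192). Lxn fell from 53.4 ± 4.00 to 27.3 ± 1.42 CPM (-0.96 ± 0.09, edgeR adjusted p = 0.00268), and Igfbp5, which binds insulin-like growth factors, fell from 213 ± 6.24 to 156 ± 1.37 CPM (-0.44 ± 0.06, edgeR adjusted p = 0.0259). Igfbp5 did not pass with a replicate block (-0.43 ± 0.09, edgeR adjusted p = 0.0774).

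Of 13423 genes, 34 differed in footprints, 30 higher and 4 lower, and 3067 had an unadjusted p under 0.05. The excess of rises was smaller or turned under other fits, with 436 higher and 384 lower with DESeq2, 138 and 105 with no filter, and 1041 and 1292 without mutant pool 2. The next falls by p, Serf1 (-0.71 ± 0.12, edgeR adjusted p = 0.0501) and Tmsb15b2 (-0.92 ± 0.15, edgeR adjusted p = 0.0511), missed the threshold. Of 22 alternatives, Serf1 passed in 13 and Tmsb15b2 in 6. Of the Hedgehog genes fixed in advance, Smo had 33.2 ± 5.17 footprint CPM in the mutant against 24.0 ± 1.67 CPM (0.49 ± 0.12, edgeR adjusted p = 0.0863) and Gli2 a log2 difference of 0.35 ± 0.09 (edgeR adjusted p = 0.0877). Gli1 stood at 0.39 ± 0.13, Gli3 at 0.14 ± 0.07, Ptch1 at 0.23 ± 0.13 and Shh at 0.50 ± 0.24, none past the threshold. Nor were Cdkn1a (0.77 ± 0.16, edgeR adjusted p = 0.0767) and Atf4 (0.16 ± 0.12). Under the alternatives Smo and Gli2 passed in 3 of 22 each, Shh in 1 of 22 and Cdkn1a in 4 of 21. The count of 34 was 8, 12 and 9 without wild-type pools 1, 2 and 3, and 35, 2333 and 18 without mutant pools 1, 2 and 3. Eif3c, Ccnd2, Lxn, Hist1h4b, Hist1h4j and Hist1h4k passed under every alternative run, whereas Trim71 did not without wild-type pool 1 (edgeR adjusted p = 0.106) or pool 3 (0.112), nor with the 4 incomplete lanes of mutant pool 1 added (0.0707). With GC offsets, chosen after seeing the data, 25 genes passed, 17 higher and 8 lower, 19 of them among the 34. Fignl2 (1.06 ± 0.21, edgeR adjusted p = 0.0796) and Hist1h2aa (1.02 ± 0.17, 0.0755) lost the call.

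As lists, histones and ribosomal proteins had higher footprints in the mutant and pan-neuronal and mitochondrially encoded genes lower ones with camera's preset correlation, and not with an estimated one. Of 24 replication-dependent histones on the list fixed in advance, 4 rose (Hist2h3b, Hist1h4b, Hist1h3d 0.76 ± 0.11 and Hist1h4h 0.60 ± 0.09). The list does not hold Hist1h4k, Hist1h4j, Hist1h2aa, Hist1h2ai and Hist1h2bp. Adjusted over the list alone 18 rose (median 0.42, camera adjusted p = 6.31e-22, adjusted p = 0.443 with an estimated correlation). Of 47 cytosolic ribosomal proteins, Rps21 (0.67 ± 0.08) and Rps10 (0.58 ± 0.08) rose. In that list 22 rose and 1 fell adjusted over the list alone (median 0.28, camera adjusted p = 1.83e-10, adjusted p = 0.443 with an estimated correlation). None of the 7 mitochondrially encoded genes passed over all genes, but all 7 fell adjusted over the list alone, among them mt-Co1 (-1.03 ± 0.20) and mt-Nd1 (-1.04 ± 0.23). Their median was -1.04 (camera adjusted p = 9.05e-10, adjusted p = 0.443 with an estimated correlation). Pan-neuronal genes had a median of -0.21, with 17 of 40 lower and 2 higher adjusted over the list alone (Mapt -0.58, Stmn2 -0.40, Map2 -0.50, camera adjusted p = 5.03e-09, adjusted p = 0.443 with an estimated correlation). Cell cycle genes had a median of 0.14 with 1 of 45, Ccnb1 (0.63 ± 0.08), past the threshold and 2 adjusted over the list alone (camera adjusted p = 3.39e-06, adjusted p = 0.613 with an estimated correlation).

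Dorsal progenitor domain factors had a median footprint change of 0.18, with 9 of 24 higher and 1 lower adjusted over the list alone, among them the roof plate ligand Wnt3a (0.86 ± 0.14, edgeR adjusted p = 0.0501), Zic5 (0.64 ± 0.11), Msx1 (0.76 ± 0.15) and Gdf7 (1.69 ± 0.34). The list passed (camera adjusted p = 9.53e-05, adjusted p = 0.443 with an estimated correlation). Ventral progenitor domain factors had a median of 0.35, with 5 of 16 higher adjusted over the list alone (Irx3 0.35, Prdm12 0.57, Sp8 0.42 and Irx5 0.91, camera adjusted p = 2.56e-04, adjusted p = 0.613 with an estimated correlation). The Wnt pathway had a median of 0.12, with 7 of 71 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00159, adjusted p = 0.443 with an estimated correlation). The Hedgehog pathway did not pass (40 genes, median 0.07, camera adjusted p = 0.181). Adjusted over the list alone, Gas1 (0.75 ± 0.14), a coreceptor of Shh, Smo and Gli2 were higher and the ciliary motor gene Kif3a (-0.35 ± 0.07) lower. Log2 differences in footprints, taken with their sign, rose with coding GC content across genes (Spearman's rho 0.423 over 12822 genes, which are not independent replicates). With GC offsets the camera adjusted p became 0.363 for dorsal factors, 0.148 for ventral factors, 0.0802 for the Wnt pathway, 0.547 for neural progenitor genes, 0.698 for the Notch pathway and 0.0802 for notochord markers.

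Several lists of other cell types had their highest summed footprints in mutant pool 1. Mesenchyme and somite markers (median 0.31 over 32 genes, camera adjusted p = 3.63e-04) summed to 3622 footprint CPM there against 2499 to 2699 CPM in the other 5 libraries, and endothelial markers (0.18, 0.0110) to 1275 against 739 to 924 CPM. There notochord markers (0.49, 0.0186) summed to 1049 against 575 to 676 CPM and erythroid markers (0.18, 0.0144, Hba-a2 rose by 0.94 ± 0.15, shared with its copy Hba-a1) to 14463 against 8445 to 10368 CPM. Without that pool their camera adjusted p was 0.131, 0.767 with the direction turned, 0.327, and 0.297 with the direction turned. Erythroid markers also lost the call without wild-type pool 1 (0.0742). In RNA, mesenchyme and somite markers of mutant pool 1 summed to 1789 CPM, within the wild-type range of 1277 to 1802 CPM. Erythroid, endothelial and notochord markers stood highest in mutant pool 1 in RNA as well. Smaller camera calls were immediate early genes (median 0.26, adjusted p = 8.18e-04) and p53 targets (0.18, 0.0101, Eda2r 1.62 ± 0.23 rose). Others were integrated stress response targets (0.09, 0.0121, 3 of 37 higher adjusted over the list alone, Phgdh 0.44, Slc7a5 0.38 and Psat1 0.31) and nuclear-encoded oxidative phosphorylation (0.05, 0.0106, Uqcr11 0.93 ± 0.11 rose, 0.344 without mutant pool 3). The last were the Notch pathway (0.12, 0.0144, 0.110 without mutant pool 2) and neural progenitor genes (0.10, 0.0471, 0.272 without wild-type pool 3, 0.0508 without mutant pool 1 and 0.580 without mutant pool 3). With an estimated correlation these 10 lists had adjusted p from 0.443 to 0.705. In all 18 of 31 lists passed with the preset correlation and 0 with the estimated one, as in RNA (12 of 30 and 0). Lists that did not pass were postmitotic spinal neuron subtype factors (median -0.06), Hox genes (-0.18, with 6 higher and 9 lower adjusted over the list alone), initiation and elongation factors other than eIF3 (0.06), eIF3 subunits (median 0.05, mean -0.03, Eif3c lower), and heat shock and unfolded protein response (0.10). Nor did the retinoic acid (0.11), BMP and TGF-beta (0.07) and FGF (-0.01) pathways or cholesterol synthesis (median 0.05, mean 0.01, test downward). Markers of surface epithelium (0.46), of neural crest, sensory ganglion and Schwann cells (0.17) and of macrophages and microglia (-0.00) did not pass either. Camera adjusted p ran from 0.154 to 0.807.

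**Figure D2:**
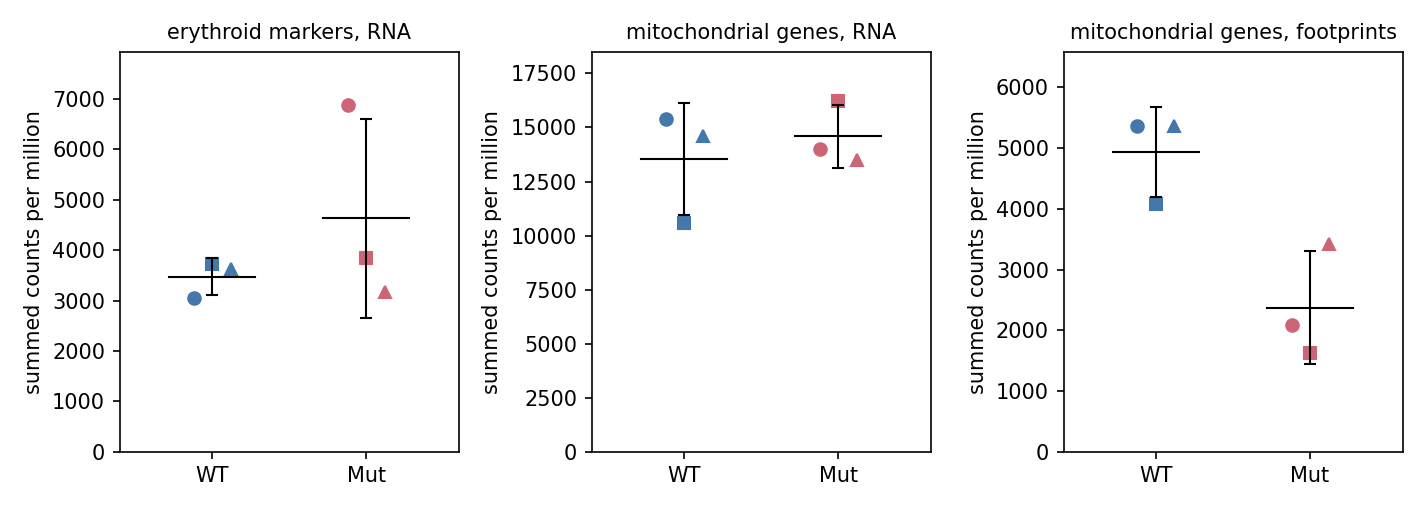
Summed CPM (TMM scaled counts) of erythroid markers in RNA and of mitochondrially encoded genes in RNA and in footprints, 1 marker per pool (circle 1, square 2, triangle 3, wild type blue, mutant red), with the mean (line) and SD (bars) of 3 pools. Mutant pool 1 stood at 6878 CPM for erythroid RNA, and mitochondrial footprints were 2375 CPM in the mutant against 4934 CPM in wild type.

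RNA and footprint changes were then compared gene by gene. Across 13010 genes tested in both, the log2 fold changes correlated with Pearson's r of 0.505 and Spearman's rho of 0.452, values across genes, which are not independent replicates. Ccnd2, Eda2r, Eif3c, Igfbp5 (RNA -0.57) and Lxn passed in both assays, each in the same direction, Igfbp5 in footprints not with the replicate block. Independent lists of these sizes would share 0.0557 genes upward and 0.00507 downward, although RNA and footprints came from the same cell pools. Of 51 genes that changed in RNA and were tested in both, 46 had the same sign in footprints, and of 28 changed in footprints 22 had the same sign in RNA. Whether a change in 1 assay and not in the other is a difference between them is the question of translational efficiency.

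Translational efficiency, the footprints of a gene relative to its RNA, was tested as the interaction of genotype and assay over all 12 libraries. The smallest p, none past the threshold, belonged to an excess of footprints for the peptidase gene Rnpepl1 (0.84 ± 0.12), for Uqcr11 of respiratory complex III (1.35 ± 0.22) and for Gdf1 (2.02 ± 0.37). Gdf1 encodes a TGF-beta family ligand and overlaps Cers1, so that its counts are uncertain. Gdf1 was also low, at a mean of 5.16 CPM over the 12 libraries, near the minimum of 5 CPM for naming. There was a deficit, not past the threshold either, for mt-Co1 (-1.17 ± 0.27), which encodes a subunit of cytochrome c oxidase inside mitochondria, for Bclaf1 (-0.43 ± 0.09) and for Cip2a (-0.40 ± 0.09). None of 13877 genes passed with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment (smallest adjusted p = 0.115, for Rnpepl1), with 1366 genes at an unadjusted p under 0.05. DESeq2 called 20 genes, limma-voom 0, and voom with sample weights and the pool as a random effect 20. Of the genes fixed in advance, Eif3c had a log2 difference of -0.22 ± 0.09 (edgeR adjusted p = 0.458), Smo of 0.41 ± 0.13 (0.430), Ptch1 of 0.36 ± 0.16 (0.494) and Gli2 of 0.28 ± 0.12 (0.470). Cdkn1a stood at 0.21 ± 0.24, Shh at 0.20 ± 0.34, Gli1 at 0.17 ± 0.18, Atf4 at 0.06 ± 0.13 and Gli3 at 0.05 ± 0.10, with edgeR adjusted p from 0.803 to 0.907. Atf4 turned negative without mutant pool 2 (-0.010) or 3 (-0.024).

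Because RNA and footprints of a pool came from the same cells, the cell pool was also fitted as a block. With that block 113 genes passed, 71 higher and 42 lower. Among them were Rnpepl1 (edgeR adjusted p = 0.00855), Uqcr11 (0.00696), Gdf1 (0.0120), Gas2l1 (0.99, 0.0204) and Tmem86b (2.01, 0.0204). Lower were mt-Co1 (-1.23, 0.0102), the zinc finger genes Zfp948 (-0.83, 0.0221) and Zfp101 (-0.51, 0.0380), Bclaf1 (-0.43, 0.0368) and Cip2a (-0.40, 0.0380). Eif3c (edgeR adjusted p = 0.158), Ptch1 (0.114), Smo (0.102), Gli2 (0.158) and the other genes fixed in advance did not pass. Of 15 alternatives to that fit, Ptch1 and Smo passed in 2 each and Gli2 in 1. The 113 were 8, 10 and 4 without wild-type pools 1, 2 and 3, and 24, 51 and 1005 without mutant pools 1, 2 and 3. Log2 differences in efficiency, taken with their sign, rose with coding GC content (Spearman's rho 0.595 over 13253 genes). With GC offsets in the same blocked fit 4 genes passed, Cdh23 (2.52 ± 0.39), Serinc2 (1.32 ± 0.17), the spliceosome gene Snrpf (0.83 ± 0.13) and Uqcr11 (1.20 ± 0.19, edgeR adjusted p from 0.0104 to 0.0361). The mutant footprint libraries all leaned to GC-rich genes against the wild-type mean (rho 0.440, 0.275 and 0.226 for pools 1, 2 and 3, against -0.187, 0.141 and 0.0130 for wild-type pools, each against the other 2). In RNA the values were -0.0331, -0.408 and -0.133 in the mutant and -0.120, 0.125 and -0.00160 in wild type.

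**Figure D3:**
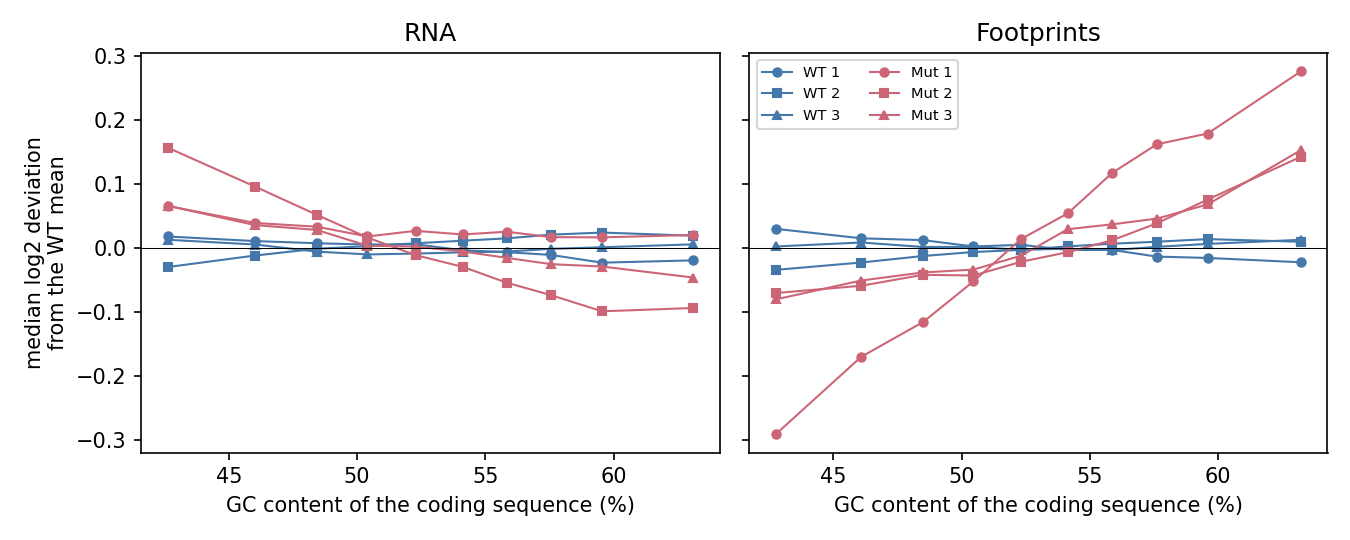
Median log2 deviation of each library from the wild-type mean, by bin of genes in GC content of the coding sequence (%, 10 bins of equal size), for RNA and footprints, 1 line per pool (wild type blue, mutant red). Mutant footprint pool 1 ran from -0.29 in the GC-poorest bin to 0.28 in the GC-richest.

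Of 31 gene lists, 7 differed in translational efficiency with the preset correlation and 0 with the estimated one. Mitochondrially encoded genes had the largest shift, a median of -1.13 over 8 genes, with mt-Nd5 at -1.32, mt-Nd4 at -1.18 and mt-Nd1 at -1.08. Adjusted over the list alone 6 were lower, and 6 over all genes with the pool as a block (camera adjusted p = 2.09e-12, adjusted p = 0.156 with an estimated correlation). In the blocked fit none of them passed over all genes with GC offsets or with the truncated lanes included. Their summed RNA was 14588 ± 1461 CPM in the mutant and 13532 ± 2586 CPM in wild type, and their summed footprints 2375 ± 935 against 4934 ± 737 CPM (SD, n = 3). Notch pathway genes had a median of 0.19 over 40 genes (camera adjusted p = 5.88e-05, adjusted p = 0.111 with an estimated correlation), with Numbl, a relative of the Notch inhibitor Numb (0.40 ± 0.10), higher adjusted over the list alone. With the pool as a block 3 rose over all genes, Numbl (edgeR adjusted p = 0.0433), the ligand gene Dll3 (0.0343) and the target Hes5 (0.53 ± 0.09 with the block, 0.0204). None of these 3 passed in that fit with GC offsets or with the truncated lanes included. Hox genes had a median of 0.17 over 36 genes with Hoxb2 (0.39 ± 0.09) and Hoxa3 (0.51 ± 0.13) higher adjusted over the list alone (camera adjusted p = 4.02e-04, adjusted p = 0.625 with an estimated correlation). The Wnt pathway had a median of 0.14 over 72 genes with none passing (camera adjusted p = 0.00174, adjusted p = 0.111 with an estimated correlation). Medians were, with camera adjusted p, for replication-dependent histones 0.28 over 24 (0.00886, 0.109 without mutant pool 3), cell cycle genes -0.08 over 45 (0.00179) and erythroid markers -0.25 over 21 (0.0265, 0.0860 without wild-type pool 3), these 3 with adjusted p = 0.857 with an estimated correlation. The histone value cannot be read as efficiency, since these mRNAs lack a poly(A) tail and the RNA libraries were made from poly(A) RNA. With GC offsets the camera adjusted p was 0.137 for Notch, 0.579 with the direction turned for Hox, 0.450 for Wnt, 0.679 for histones and 0.461 for cell cycle genes. The mitochondrially encoded and erythroid lists kept their calls.

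The Hedgehog pathway did not pass in efficiency. Its 40 genes had a median of 0.12, 28 positive and 12 negative, with Gas1 (0.71 ± 0.17) the only one higher adjusted over the list alone (camera adjusted p = 0.0710, adjusted p = 0.830 with an estimated correlation). With the pool as a block Gas1 rose over all genes (edgeR adjusted p = 0.0440) and the list stayed short of the threshold (camera adjusted p = 0.0727). Gas1 did not pass in the blocked fit with GC offsets or with the truncated lanes included. That block added 2 lists, mesenchyme and somite markers (0.27, camera adjusted p = 0.00197 against 0.0686) and initiation and elongation factors other than eIF3 (median -0.05, 0.0472 against 0.0567). With an estimated correlation in the blocked fit they had adjusted p = 0.658 and adjusted p = 0.702. The other lists had camera adjusted p from 0.0710 to 0.885 and medians from -0.06 for eIF3 subunits to 0.22 for surface epithelium. Median and test differed in sign for the FGF pathway (0.05), p53 targets (0.02), heat shock and unfolded protein response (0.02) and cholesterol synthesis (-0.02), where the test pointed the other way.

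**Figure D4:**
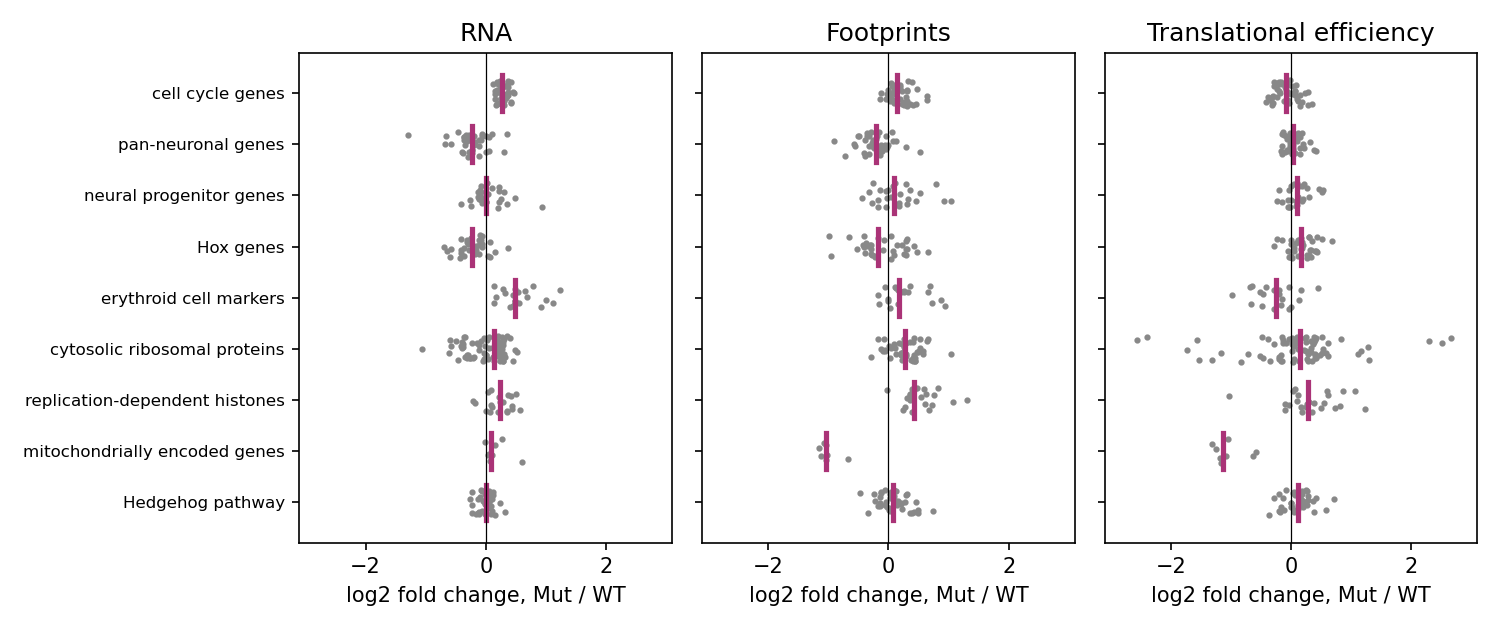
Log2 fold change, mutant against wild type, of each measured member (grey points) of 9 gene lists in RNA, footprints and translational efficiency, with the list median (purple bar). Cell cycle genes lie above 0 in RNA with a median of 0.26, and mitochondrially encoded genes at -1.04 in footprints.

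The last comparison described wild-type neural tube alone: which mRNAs carried more or fewer footprints per RNA, relative to the average gene. The ratio compares 2 kinds of library, and no offsets for GC content or coding length were tried on it. Differences between the 2 protocols can therefore not be told from differences in translation. The 24 replication-dependent histones were all higher, with a median log2 ratio of 6.96 (camera adjusted p = 5.95e-83, adjusted p = 0.00884 with an estimated correlation). Their mRNAs end in a stem-loop in place of a poly(A) tail, and the RNA libraries were made from poly(A) RNA. There they summed to 92.9 ± 5.03 CPM against 10971 ± 1247 CPM in footprints. Nuclear-encoded oxidative phosphorylation genes were higher (median 0.62, 63 of 75 higher and 4 lower, camera adjusted p = 5.69e-10, adjusted p = 0.717 with an estimated correlation). So were heat shock and unfolded protein response (0.68), pan-neuronal (0.67), cholesterol synthesis (0.61), mesenchyme and somite (0.61), eIF3 subunits (0.54, 9 of 13 higher), neural progenitor (0.45) and cell cycle genes (0.42), with camera adjusted p from 1.86e-04 to 0.0338 and adjusted p = 0.717 or 0.799 with an estimated correlation. Cytosolic ribosomal proteins were lower (median -1.62, 69 of 80 lower and 2 higher, camera adjusted p = 2.92e-13, adjusted p = 0.717 with an estimated correlation). All 80 passed the filter in the RNA fit but 47 in the footprint fit, and 71 had any footprint count. Footprint reads lost because they fit several genes cannot be told from low translation here. The Hedgehog pathway was lower as well (median -0.55, 26 of 40 lower and 7 higher, camera adjusted p = 0.00403, adjusted p = 0.717 with an estimated correlation). For the genes fixed in advance, the log2 ratio was 0.69 ± 0.06 for Eif3c, above 83.5% of genes, but -4.30 ± 0.09 for Atf4, whose upstream reading frames are known to hold back its translation, above 1.10% of genes. Smo (-2.37 ± 0.09), Gli1 (-2.22 ± 0.13) and Ptch1 (-1.80 ± 0.12) lay above 3.53%, 4.05% and 6.42% of genes. Gli3 (-0.59 ± 0.07) and Gli2 (-0.39 ± 0.08) lay above 27.3% and 33.8%, and Cdkn1a (0.44 ± 0.18) above 71.1%, each past the threshold (edgeR adjusted p from 1.86e-13 to 0.0364), while Shh (0.26 ± 0.24, edgeR adjusted p = 0.337) was not. The other 20 lists did not pass, among them mitochondrially encoded genes (-1.37, camera adjusted p = 0.123). In 5 of the 20 the median and the mean or the test differed in sign. These were initiation and elongation factors other than eIF3 (0.14 and -0.40), the Notch pathway (0.03 and -0.17), the BMP and TGF-beta pathway (0.18 and -0.02), integrated stress response targets (0.47 and -0.03) and notochord markers (0.26 and -0.07). In all, 9960 of 13877 genes differed, 4925 higher and 5035 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

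Y-linked genes were used to see whether the sexes of the pooled embryos differed. Ddx3y, Eif2s3y, Kdm5d and Uty summed to 292, 262 and 8.21 RNA CPM in wild-type pools 1 to 3 and to 330, 152 and 5.33 CPM in mutant pools 1 to 3. Pool 3 of both genotypes thus held almost no RNA of Y-linked genes. Xist, which female cells transcribe from the inactive X chromosome, was 1519, 2309 and 6357 CPM in wild type and 1653, 4981 and 7138 CPM in the mutant. None of the 4 Y-linked genes passed between the genotypes in RNA (edgeR adjusted p from 0.903 to 0.947).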

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

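All tests of this part were chosen after the results of the comparisons were seen, and each prediction was written before its test was run, except that of the fewer-neurons test, written after. The list of neuronal factors of later onset was also written after the data were seen. Footprints counted in untranslated regions, which no comparison used, stood out because their share was above that of wild type. In 5' untranslated regions it was 14.3 ± 1.23% in the mutant against 12.8 ± 0.0444% in wild type (n = 3), and in 3' untranslated regions 1.97 ± 0.751% against 1.53 ± 0.0395%. The parts summed to 105% of the counts of whole transcripts, so that some reads were counted in more than 1 part. The 5' counts may therefore hold footprints on the start codon. The excess was uneven between pools: mutant pools 1, 2 and 3 had 15.2%, 12.9% and 14.7% in 5' regions, pool 2 barely above the highest wild-type pool (12.885% against 12.859%), and 1.43%, 2.83% and 1.65% in 3' regions, where it came mostly from pool 2. Per gene, 5' counts and coding counts (without the first 15 and last 5 codons) were each scaled to their own totals. The ratio was thus tested relative to the average gene, with the excess common to all genes removed. This ratio of 5' untranslated to coding footprints differed for 644 of 13243 genes (407 higher, 237 lower, edgeR's quasi-likelihood test, adjusted p under 0.05), against 5 genes of 12738 for RNA. The percentages that follow are of unscaled counts, and the log2 changes are of scaled ones. Atp5k, of the ATP synthase, went from 6.32% to 33.1% of its coding footprints (2.32 ± 0.24, edgeR adjusted p = 9.80e-06), and the histone gene Hist2h3b from 744% to 306% (-1.51 ± 0.14, edgeR adjusted p = 2.36e-06). Of 24 replication-dependent histones, 13 were lower and 1 higher. Their coding footprints, the divisor of the ratio, were higher in the mutant (list median 0.42). Those of Hist2h3b rose by 1.31 ± 0.12, but by 0.26 ± 0.17 with whole coding sequences. Lower ratios of histones thus need not be a change in 5' footprints, and reads of near-identical copies can be shared. None of the genes fixed in advance passed, with Shh at -0.49 ± 0.16 (edgeR adjusted p = 0.0796) and Atf4 at -0.33 ± 0.15 (0.208). The ratio followed the difference in GC content between the 2 parts (rho 0.337), and 536 genes passed with GC offsets. The 644 were 92, 652 and 260 without wild-type pools 1, 2 and 3, and 418, 1014 and 343 without mutant pools 1, 2 and 3.

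Cell cycle RNA was higher and pan-neuronal RNA lower in the mutant as lists, with 4 of 45 and 0 of 40 genes past the threshold over all genes and adjusted p = 0.558 for both lists with an estimated correlation. Blood and other non-neural cells of mutant pool 1 were argued against, since without that pool the cell cycle median was 0.24 (95% bootstrap interval over genes, which are correlated, 0.22 to 0.28, against 0.26) and the pan-neuronal median -0.19 (interval -0.24 to -0.12, against -0.23), while the erythroid median fell from 0.48 to 0.07. A lower share of neurons predicts progenitor genes higher by about as much. The neural, ventral and dorsal progenitor lists joined had a median of 0.137 (interval 0.01 to 0.22, SD over genes 0.356), with 0.01 for neural, 0.19 for ventral and 0.20 for dorsal. The interval lies under the cell cycle median of 0.26. The rule also asked for a difference above the SD over genes, which it could hardly reach, so that the test decides nothing. A lower share of neurons stays open. Mutant embryos at an earlier stage would have less of the neuronal factors of later onset, and the difference of their median from the pan-neuronal median was -0.148 (interval -0.25 to -0.01, 10 genes, none past the threshold, with Neurod2 in both lists), but 0.01 without mutant pool 1 (interval -0.18 to 0.09) and -0.10 without wild-type pool 3 (interval -0.26 to 0.05), so that an earlier stage stays open too, as does slower neuronal differentiation caused by the genotype, untested here. Genes picked after the data were seen had the signs of an earlier stage, with the early genes Lin28a (0.48), Hmga2 (0.35), Lin28b (0.31) and Igf2bp1 (0.22) positive and the later Fabp7 (-0.41), Sox9 (-0.27) and Slc1a3 (-0.25) negative, but none passed (edgeR adjusted p from 0.138 to 0.356) and picked genes decide nothing.

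With the cell pool as a block, 113 genes differed in translational efficiency. Coding length was argued against as a bias: 108 of the genes were called again with length offsets (rho -0.00348). A GC bias of the footprint libraries was not: 4 were called again with GC offsets, the rho was 0.594 over 13253 genes, genes called higher had a median GC of 63.2% and those called lower of 41.4% against 53.3% for all, and the median absolute change went from 0.51 to 0.32 with the standard error at 0.10 and 0.11. Whether translation itself differs between GC-rich and GC-poor mRNAs in the mutant, in which case the offsets would remove biology, stays open.

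As a list, mitochondrially encoded genes had lower footprints in the mutant (median -1.04, adjusted p = 0.443 with an estimated correlation, 0 of 7 past the threshold over all genes), with an RNA median of 0.09. GC content was argued against, as 184 nuclear genes of the same GC range (33.0% to 39.9%) had a median efficiency change of -0.34 against -1.13. A difference in how far mitochondria were spun out of the footprint lysates stays open: the spread over genes was 0.651 of the standard error, which decides nothing, since the genes share most of that error (estimated correlation 0.940). Lower mitochondrial translation in the mutant, in which nuclear-encoded oxidative phosphorylation genes had a median footprint change of 0.05, stays open as well, untested.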

How the results depend on the processing

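Eif3c was lower and past the threshold in RNA and footprints under every alternative (leave-one-out edgeR adjusted p 9.01e-05 to 0.0255 in RNA and 8.01e-04 to 0.0194 in footprints). Of the 20 genes named as changed in RNA, 1 stayed past the threshold without any 1 of the wild-type pools or without mutant pool 3, and 19 and 20 without mutant pools 1 and 2. Of 13 in footprints, 8 stayed without any 1 of the wild-type pools, and 12, 13 and 11 without mutant pools 1, 2 and 3. At a fold of 1.5, 68% of changes simulated without pool effects were found in RNA and footprints and 44% in efficiency. Counts of genes moved far more, and the cause was not tested. RNA (52 genes) gave 395 with DESeq2, 87 with limma-voom, 462 with no filter, 86 with run 2 alone, 1 with transcripts summed per gene, 269 with all transcripts tested, 5 in the fit of 12 libraries, 22 with whole coding sequences, 2 with GC offsets, and 1 to 1528 leaving out 1 pool. Footprints (34) gave 820 with DESeq2, 130 with limma-voom, 243 with no filter, 105 with run 2 alone, 22 with transcripts summed, 94 with all transcripts, 509 in the fit of 12 libraries, 9 with the truncated lanes, 59 with whole coding sequences, and 8 to 2333 leaving out 1 pool. Translational efficiency (0) gave 20 with DESeq2, 16 with a block and DESeq2, 20 with voom weights and pools as a random effect, 113 with the cell pool as a block, and 0 to 1 leaving out 1 pool; with that block (113) it gave 71 with DESeq2, 679 with no filter, 74 with a filter of 1 CPM, 0 with the truncated lanes, 4 with GC offsets, 386 with length offsets, 54 with run 2 alone and 4 to 1005 leaving out 1 pool. In wild type the count stayed from 8607 to 10770. The ratio of 5' untranslated to coding footprints (644) gave 92 to 1014 leaving out 1 pool. With a replicate block, the replicate number shared by the genotypes, there were 196 genes in RNA (198 with DESeq2) and 38 in footprints (225 with DESeq2); the genotypes' equal numbers correlated at 0.105, 0.0566 and 0.0740 in RNA, where every library correlated best with its own number, and at -0.0854, -0.0751 and -0.0264 in footprints, where none did.

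Gene list calls fell to 0 in RNA, footprints and efficiency with an estimated correlation, and were 0, 2 (1 of them shared) and 2 (both shared) with fry, which tests a list against no change; in efficiency, GC offsets left 4, 2 of them shared. Without mutant pool 1 the direction turned for ribosomal proteins in RNA (adjusted p 0.132, leave-one-out range 4.05e-07 to 0.266), and in footprints for erythroid (0.297, range 4.55e-05 to 0.297) and endothelial markers (0.767, range 2.06e-04 to 0.767). It turned for Hox genes in efficiency with GC offsets (0.579). Log2 values turned for Gli2 in RNA (-0.0032 without mutant pool 3, leave-one-out up to 0.128) and for Atf4 in footprints (-0.051, whole coding sequences). Atf4 in efficiency turned without mutant pools 2 (-0.010) and 3 (-0.024, leave-one-out up to 0.211) and with whole coding sequences (-0.14). With the pool block it was -0.015 without mutant pool 3 (up to 0.225) and -0.13 with whole coding sequences. Shh in efficiency was -0.14 with run 1 alone and -0.037 with GC offsets, and with the pool block -0.0088 without wild-type pool 1 (up to 0.297) and -0.059 with GC offsets. None of these genes passed in the comparison concerned; the cause was not tested.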

Other observations

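The tests of this part were splits of the pools, with predictions written before the splits were run; that of the 5' untranslated ratio was chosen after seeing the results. The 10 ways to divide 6 pools 3 and 3, or, for wild-type efficiency, the 6 wild-type libraries of both assays, cannot give a share under 0.05, so that the real grouping and a chance one cannot be told apart by them. The real grouping had 52 genes in RNA, 34 in footprints, 113 in efficiency with the pool as a block, 9960 in wild-type efficiency and 644 for the 5' untranslated ratio, against 0 in every other split, so that 1 split of 10 reached each count; in efficiency without the block all 10 splits gave 0. Lists were also called in other splits: 8 of 10 splits gave at least the 12 lists of RNA (highest other 17), 1 the 18 of footprints (16), 4 the 7 of efficiency (9) and 9 the 11 of wild type (16).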
